A study of Mus musculus with 8 samples.

How the data were processed

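RNA of sorted eosinophils was sequenced in 8 libraries, made by CEL-Seq and read on an Illumina NextSeq 550 instrument per the labels' extract protocol. Each library has 1 deposited table of whole-number counts per Ensembl gene, which the authors made from their reads without normalization, as the unequal library totals show. The submitters' processing notes name FastQC 0.11.5, Trim Galore with cutadapt 1.10, TopHat2 2.1.0 with Bowtie2 2.2.6, HTSeq 0.6.1 and DESeq2 1.28.0, without settings. The genome build, the annotation release, the strand setting and whether molecular identifiers were collapsed are not given in the sources used here. If reads rather than molecules were counted, copies made in amplification add to the spread between libraries, and intervals from counts are then too narrow. CEL-Seq reads fall near transcript ends, so a count says little about the rest of a transcript, and genes with near-identical copies (the Ear family with Rnase2a, Chil3 with Chil4, haemoglobin genes) or overlapping partners may share reads.

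All tables held the same 54446 gene rows, of which 54409 matched a symbol by Ensembl identifier in the GENCODE mouse reference on GRCm38, also the source of gene positions, and 37 did not. A total of 21197 genes had a count in at least 1 library. Groups were taken from sample titles alone: resident (n = 4), Siglec-Fint/CD101- (n = 2) and SiglecFhi/CD101+ (n = 2). The deposited tables carry the letter N for resident, R for Siglec-Fint/CD101- and I for SiglecFhi/CD101+ samples, which the labels do not explain, so R need not stand for the group titled resident. Low Epx, Il5ra and Siglecf beside high MHC class II genes leave the purity of the sorted cells and the match of labels to tables uncertain, and all values are those of the labelled groups. The labels give no sex, no treatment and no animal for any sample. A count of 3 in a library, used as its floor, equals 0.199 to 0.501 CPM in resident libraries and 1.59 to 2.18 CPM in subset libraries, and folds against a group without counts were set against 3 counts over that group.

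The 3 comparisons between groups were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, a group-means model over all 8 libraries without a block, robust quasi-likelihood fits and two-sided tests, called at a Benjamini-Hochberg adjusted p under 0.05. The filter kept 11828 genes, and the common biological coefficient of variation was 1.12. CPM values are scaled by TMM-adjusted library sizes. Ratios of genes with few counts carry exact 95% counting intervals. Gene lists were also fixed before the data were examined: 35 lists, 25 of pathways or programmes and 10 of markers of other cell types, each tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Adjusted p-values of lists are Benjamini-Hochberg adjusted over the lists of a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone.

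Genes named in the text follow a rule set in advance. In each comparison it takes, among genes past the threshold, those with a mean log2 CPM at or above the median of tested genes (3.05), no overlap of the groups' CPM values, and a symbol that is neither a predicted gene model, a ribosomal pseudogene nor an antigen receptor segment. The 10 largest changes in each direction are named, or, where none passes, the 3 smallest p-values as values that did not pass. Siglecf, Cd101 and Il5ra are reported in every comparison, 1 further gene of the rule is not reported here, and from each list up to 4 members with the smallest p may be named. Other genes are marked as chosen after their values were seen.

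The procedures were tested on simulated data with the real library sizes, in which 200 genes of at least median level were changed 4-, 16- or 64-fold. Before these changes each gene had 1 mean and 1 spread, estimated from the data, for all 8 libraries. The real subset libraries agreed less with each other than the resident libraries did, so rates in the real groups may differ. In runs with this pooled spread, 1 to 5 unchanged genes were called per comparison. Alternatives tried were RLE, upper-quartile and no normalization factors, DESeq2 1.42.0, limma-voom, non-robust fits, no filter, a filter of 20 counts in 2 libraries, an adjusted p under 0.01, glmTreat against a log2 fold change of 1, thinning to 1513517 counts per library, fits on the compared groups alone, a replicate block, and leaving out each library in turn. For lists, fry was run as well. Overlap of calls against the shared resident libraries was set against 20 simulations without an effect.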

Results

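In a study of a mouse model of asthma, sorted eosinophils were profiled by CEL-Seq, a method that reads the 3' ends of transcripts after linear amplification. The labels give no treatment for any sample, so a difference in treatment between the groups cannot be told apart from the groups. The 8 libraries, all from C57BL/6 mice, fell into 3 groups by their labels. Resident eosinophils had 4 libraries (replicates 3 to 6). The other libraries came from subsets defined by Siglec-F, a sialic acid-binding lectin of the eosinophil surface, and CD101, an immunoglobulin-like surface protein: Siglec-Fint/CD101- eosinophils (n = 2) and SiglecFhi/CD101+ eosinophils (n = 2). Total counts ranged from 5600610 to 11583550 in resident libraries, were 1517159 and 2990294 in the Siglec-Fint/CD101- libraries, and were 3109428 and 1513517 in the SiglecFhi/CD101+ libraries. Genes of the mitochondrial genome took 52.4% ± 10 of the counts in resident libraries (SD, n = 4), 76.9% ± 9.90 in Siglec-Fint/CD101- libraries (n = 2) and 76.4% ± 8.20 in SiglecFhi/CD101+ libraries (n = 2). Counts outside those genes ranged from 2137819 to 5296468 in resident libraries and from 444902 to 552121 in the 4 subset libraries. Between 12700 and 15997 genes were detected per resident library, against 7356 and 8514 in Siglec-Fint/CD101- and 10834 and 9238 in SiglecFhi/CD101+ libraries. Spearman correlations of log2 CPM were 0.70 to 0.78 between resident libraries, 0.43 between the Siglec-Fint/CD101- libraries and 0.41 between the SiglecFhi/CD101+ libraries. Correlations between libraries of different groups were 0.38 to 0.55, so the libraries of a subset were about as far from each other as from other groups. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical. Means below are CPM (counts scaled to library size) ± SD over those 4, 2 and 2 libraries. Fold changes carry an approximate standard error (SE), the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Counting intervals and floors cover counting error only. Folds written as at least take 3 counts for a group with 0. Exact 95% lower limits were smaller, such as 19.4 against 23.9 for Stat5a in SiglecFhi/CD101+ against resident libraries.

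**Figure D1:**
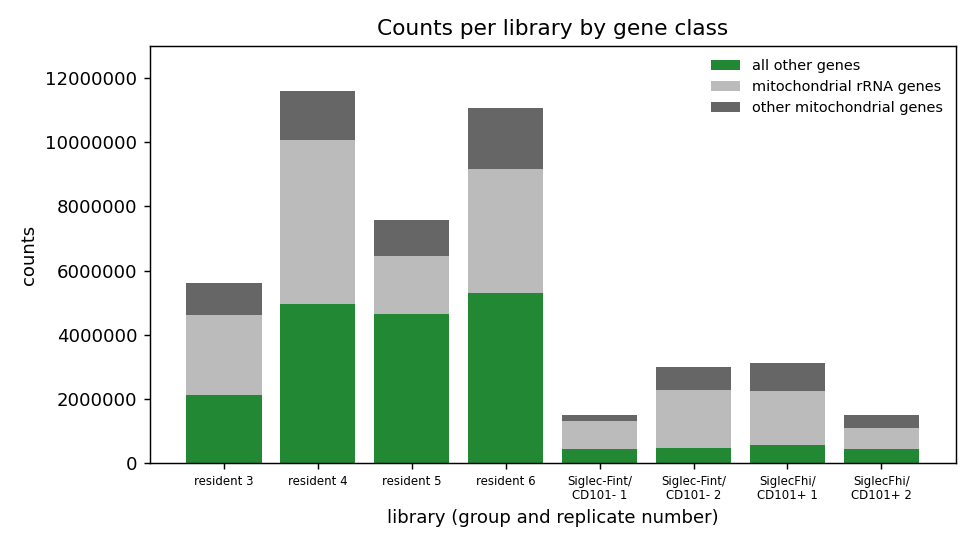
Stacked bars give the counts of each of the 8 libraries, divided into mitochondrial rRNA genes, other mitochondrial genes and all other genes, by group and replicate number. The part outside mitochondrial genes is at least 2137819 counts in each resident library and at most 552121 counts in each subset library.

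The transcripts of the sort markers were low in every group, so the share of eosinophil RNA in a library is not known and group names are those of the labels. Siglecf was at 20.2 ± 17.0 CPM in resident and 18.5 ± 11.9 CPM in SiglecFhi/CD101+ libraries, and it had 0 counts in both Siglec-Fint/CD101- libraries. Against a floor of 3 counts over the group, this put Siglec-Fint/CD101- libraries at least 20.5-fold below resident and at least 17.8-fold below SiglecFhi/CD101+ libraries. Cd101 had 1095 counts over the resident libraries (24.3 ± 13.8 CPM), 1 count over the Siglec-Fint/CD101- libraries and 3 counts over the libraries labelled SiglecFhi/CD101+. The resident level of Cd101 was thus 26.8-fold the SiglecFhi/CD101+ level (95% counting interval 9.15 to 130) and 68.1-fold the Siglec-Fint/CD101- level (12.2 to 2690). Il5ra, the alpha chain of the IL-5 receptor, had 58 counts over the resident libraries and 0 over either subset, too few to be tested. Epx, the eosinophil peroxidase gene, chosen after its values were seen, had 25 counts, all in resident replicate 5. Neither Siglecf nor Cd101 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in any of the 3 comparisons, with a smallest adjusted p of 0.235 for Siglecf between the subsets. The small difference of SiglecFhi/CD101+ from resident libraries in Siglecf, a log2 fold change of -0.13 ± 1.32 (SE), changed sign with RLE (0.36) and with upper-quartile normalization (0.09).

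The first comparison asked how SiglecFhi/CD101+ eosinophils differ from resident eosinophils. Retnla (ENSMUSG00000061100; chromosome 16, 48842551 to 48844461, GRCm38), which encodes the secreted protein resistin-like alpha, a target of IL-4 and IL-13, rose from 41.2 ± 28.7 CPM in resident to 1750 ± 1090 CPM in SiglecFhi/CD101+ libraries, a log2 fold change of 5.41 ± 0.61 (SE; adjusted p = 0.00124). Igha, the constant region of the IgA heavy chain, rose from 3.63 ± 5.38 to 770 ± 905 CPM (7.71 ± 1.19; adjusted p = 0.041). Gm26870, a long noncoding RNA gene annotated in a repeat-rich region at the start of chromosome 9, rose from 58.1 ± 27.0 to 4510 ± 3740 CPM (6.28 ± 0.55, and from 4.91 to 6.87 with 1 library left out; adjusted p = 0.000102), and its reads cannot be placed with certainty. Igha and Gm26870 lie outside the rule for named genes and were chosen after their values were seen. These were the 3 genes of 11828 tested that were higher, and 0 were lower, by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 432 higher and 1552 lower genes, where chance gives 591 in all. DESeq2 called 499 higher and 577 lower genes, and limma-voom 2 higher and 0 lower. The 3 lower genes with the smallest p did not pass: Higd2a, an assembly factor of cytochrome c oxidase, with 5858 counts in resident and 4 in SiglecFhi/CD101+ libraries (adjusted p = 0.0585), the class II gene H2-Ab1 (0.0682), and Fmnl1, a formin of leukocytes, with 6032 and 6 counts (0.0682). The median log2 fold change of all tested genes was -0.72 with TMM scaling and moved between -1.46 with library totals alone and -0.26 with RLE normalization. It was -3.15 and -2.12 without SiglecFhi/CD101+ replicate 1 or 2, where the filter kept 14609 and 14727 genes, so the place of a gene group among other genes depends on these choices. Without SiglecFhi/CD101+ replicate 1, Retnla had an adjusted p of 0.0584 at a log2 fold change of 4.49. Leaving out resident replicate 3 or 6 or either SiglecFhi/CD101+ library raised the adjusted p of Igha to 0.2, 0.0879, 0.0584 and 0.107. Its log2 fold change was 7.51, 7.61 and 8.5 in the first 3 of these, and 5.06 without SiglecFhi/CD101+ replicate 2.

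Genes of antigen presentation by MHC class II were lower in SiglecFhi/CD101+ than in resident libraries. H2-Aa and H2-Ab1, which encode the chains of the I-A molecule, were at 9620 ± 4390 and 6560 ± 2500 CPM in resident libraries and at 1930 ± 102 and 1370 ± 108 CPM in SiglecFhi/CD101+ libraries. Their log2 fold changes were -2.32 ± 0.50 and -2.26 ± 0.39. H2-Eb1, a chain of I-E, changed by -2.22 ± 0.48 and Cd74, the invariant chain that escorts class II molecules, by -2.24 ± 0.44. Of the 13 tested members of the class II list, 7 fell and 0 rose adjusted over the list alone (adjusted p = 0.000401 for H2-Ab1). Over all genes tested 0 passed, with H2-Ab1 closest at an adjusted p of 0.0682. Of 22 alternatives, H2-Ab1 passed over all genes in 7, Cd74 in 5, H2-Eb1 in 4 and H2-Aa in 3. The list's median log2 fold change was -2.22 and its mean -1.59, and limma's camera placed the list below other genes (adjusted p = 0.0275, and adjusted p = 0.751 with an estimated correlation). The camera call was lost with RLE normalization (adjusted p = 0.0795; median -1.74), and without resident replicate 3 (0.11; -2.18), 4 (0.186; -1.81) or 6 (0.102; -2.05) or SiglecFhi/CD101+ replicate 2 (0.0527; -2.01), while the list's median stayed near its size. Without SiglecFhi/CD101+ replicate 1 or 2 the list's medians (-2.48 and -2.01) lay above the all-gene medians of those fits (-3.15 and -2.12). Markers of dendritic cells, which carry much class II RNA, summed to 202.5 ± 43.1 CPM in resident and 113 ± 37.8 CPM in SiglecFhi/CD101+ libraries.

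Type 2 genes went both ways in this comparison. Chil3 (chromosome 3, 106147554 to 106167564), which encodes the chitinase-like protein Ym1, rose from 604 ± 109 to 1950 ± 275 CPM (1.69 ± 0.38), and its close paralog Chil4, whose reads may be shared with it, rose from 0.825 ± 1.55 to 42.0 ± 11.9 CPM (5.59 ± 1.30, and from 5.18 to 9.18 with 1 library left out). Ccl17, a chemokine that draws T helper cells, fell from 137 ± 53.1 to 18.5 ± 4.59 CPM (-2.89 ± 0.90). Of the 16 tested members, 4 rose and 5 fell adjusted over the list alone (adjusted p = 3.36e-06 for Retnla, 0.00338 for Chil3 and for Chil4, 0.0199 for Ccl17), and Retnla alone passed over all genes. The list's median was -1.20, or -0.53 with members at 0 counts set to their bound, its mean was -0.91, and camera's direction was up without passing (adjusted p = 0.263).

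Protein genes of the mitochondrial genome, all encoding subunits of the respiratory chain or ATP synthase, rose together with the share of mitochondrial counts. Adjusted over the list alone, 12 of 13 rose, with log2 fold changes of 1.69 ± 0.39 for mt-Nd2 (from 0.96 to 2.04 with 1 library left out) and 1.80 ± 0.45 for mt-Nd4. Over all genes 0 passed. The list's median was 1.45 (camera adjusted p = 3.12e-09, and adjusted p = 0.751 with an estimated correlation), and 0.93 without SiglecFhi/CD101+ replicate 1. Markers of endothelial cells and fibroblasts summed to 2894 ± 1555 CPM in resident and 3660 ± 934 CPM in SiglecFhi/CD101+ libraries. Their list had a median of 0.18 above the all-gene median of -0.72 (camera adjusted p = 0.0275, and adjusted p = 0.751 with an estimated correlation), with 0 of 19 members past the threshold over all genes or over the list alone. Without resident replicate 4 (0.186) or 6 (0.0741) or SiglecFhi/CD101+ replicate 2 (0.234) that call was lost. The list's median ranged from 0.09 without SiglecFhi/CD101+ replicate 1 to 0.63 without resident replicate 5, and was 0.63 with RLE normalization.

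In the edgeR fit over all 8 libraries, several receptors and signalling genes of granulocytes passed only adjusted over the list alone. Prg2, which encodes major basic protein, the core of the eosinophil granule, rose from 8.55 ± 5.07 to 137 ± 139 CPM (4.00 ± 0.95; adjusted p = 0.00303 among 4 tested granule genes). Without SiglecFhi/CD101+ replicate 2 its log2 fold change was 2.08. Ear2, an eosinophil-associated ribonuclease whose reads may be shared with its paralogs, was at 213 ± 68.3 and 83.1 ± 51.5 CPM and did not pass. In the IL-5, IL-3 and GM-CSF signalling list, 3 of 18 members fell. They were Socs3, a feedback inhibitor of cytokine signalling (-3.63 ± 0.82), Csf2ra, the GM-CSF receptor alpha chain (-4.85 ± 1.12, and from -8.55 to -3.98 with 1 library left out), and Stat5a, a transcription factor activated by these cytokines. Stat5a had 975 counts in resident and 0 in SiglecFhi/CD101+ libraries, at least 23.9-fold lower. Among 26 adhesion and chemotaxis genes, 3 fell: Itgb2, the beta-2 integrin chain (-2.35 ± 0.60), Selplg, the P-selectin ligand (-2.28 ± 0.62), and Fpr1, a formyl peptide receptor. Fpr1 had 1554 and 0 counts (at least 38-fold lower). Log2 fold changes with 1 library left out ran from -3.36 to -1.88 for Itgb2 and from -4.51 to -3.07 for Socs3. Among 27 NF-kB targets and inflammatory cytokines, 3 fell, of which Il1b went from 409 ± 141 to 92.3 ± 72.1 CPM (-2.15, and from -3.40 to -1.60 with 1 library left out) and Cd83 from 305 ± 107 to 68.4 ± 6.76 CPM. The inducible heat shock genes Hspa1b (-1.88 ± 0.49) and Hspa1a (-1.82 ± 0.55) were among 4 of 31 members of their list that fell. Nfe2l2, the antioxidant regulator NRF2, fell by 2.50 ± 0.70 on the log2 scale, while Slc7a11, a cystine transporter it controls, rose by 2.54 ± 0.74, but by only 0.82 without SiglecFhi/CD101+ replicate 2. Ptger4, the prostaglandin E receptor EP4, had 2577 counts in resident and 1 in SiglecFhi/CD101+ libraries, a ratio of 189 (33.9 to 7480). In the 13 eosinophil receptors and lineage factors 0 passed over all genes or over the list alone, and in the resident-subset and inflammatory-subset lists, written from general knowledge of lung eosinophil subsets, 1 of 6 and 4 of 7 members fell adjusted over the list alone. By fry, which does not compare a list with other genes, 10 lists passed, all lower in SiglecFhi/CD101+ libraries and none of them called by camera, with dendritic cell markers and cholesterol genes at the smallest adjusted p (0.0121 each). In all, 17 of 35 lists held a member that passed over the list alone, and the 32 lists without a camera call had a smallest adjusted p of 0.0628. With simulated data of the pooled spread, 4-fold changes in this comparison were recovered in 0% of genes, 16-fold in 26.9% and 64-fold in 56.1%.

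**Figure D2:**
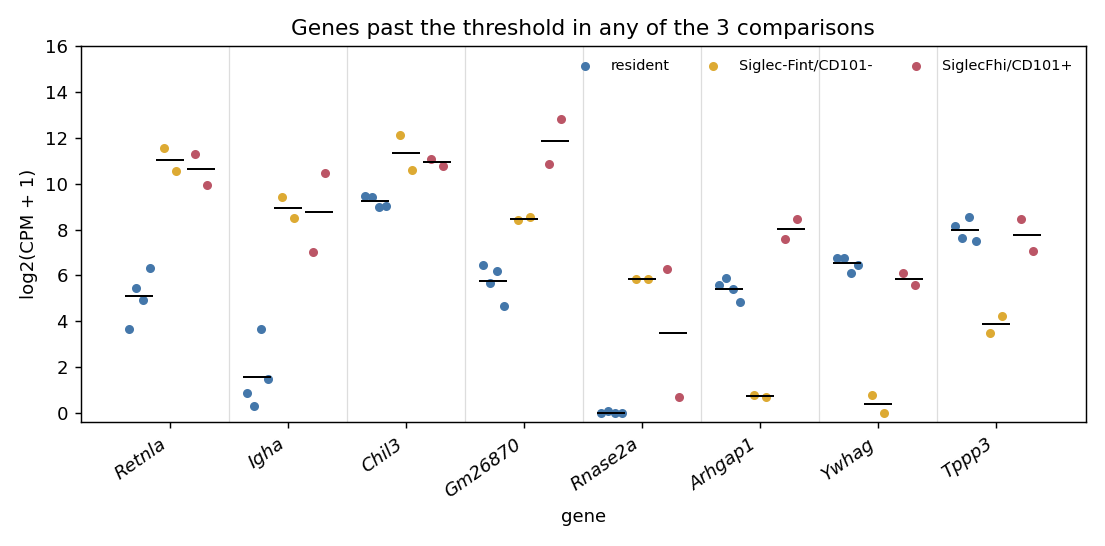
Points are single libraries and black lines group means of log2(CPM + 1) for the 8 genes past the threshold in any comparison, coloured by group. Retnla lies at or below 79.7 CPM in the 4 resident libraries and at or above 982 CPM in the 4 subset libraries.

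The second comparison set Siglec-Fint/CD101- against resident eosinophils. Retnla rose to 2240 ± 1050 CPM (5.77 ± 0.61; adjusted p = 0.00129), and Chil3 to 2990 ± 2060 CPM (2.31 ± 0.38; adjusted p = 0.0409). Rnase2a, an eosinophil-type ribonuclease of the Ear family whose reads may be shared with its paralogs, had 169 counts in Siglec-Fint/CD101- and 1 in resident libraries, a ratio of 2720 (481 to 108000). Tppp3, which encodes a tubulin polymerization-promoting protein, fell from 259 ± 87.1 to 14.1 ± 5.53 CPM (-4.19 ± 0.70). Ywhag, the adaptor protein 14-3-3 gamma, had 4288 counts in resident and 1 in Siglec-Fint/CD101- libraries, a ratio of 267 (47.8 to 10500), and Arhgap1, a GTPase-activating protein, had 2027 and 2 counts, a ratio of 63 (17.4 to 521). With Igha, which rose to 520 ± 226 CPM (7.14 ± 1.17) and was again chosen after its values were seen, 4 genes rose and 3 fell of 11828 by edgeR's quasi-likelihood test, each but Retnla at an adjusted p of 0.0409. At an unadjusted p under 0.05 there were 225 higher and 1637 lower genes, where chance gives 591 in all. DESeq2 called 106 higher and 522 lower genes, and limma-voom 2 higher and 0 lower. The median of all genes was -0.997, between -1.96 and -0.63 under other scalings, and -3.29 and -4.42 without Siglec-Fint/CD101- replicate 1 or 2, where the filter kept 14968 and 14962 genes. With 1 library fewer, 1 gene was called without resident replicate 3, 2 without resident replicate 4, 3 without resident replicate 5, 1 without resident replicate 6, and 0 and 2 without Siglec-Fint/CD101- replicates 1 and 2. Log2 fold changes moved little for Arhgap1 (-6.15 to -5.76), Rnase2a (10.10 to 11.43) and Tppp3 (-4.68 to -3.89) while their calls were lost, and more for Ywhag (-12.47 to -6.98) and Igha (6.56 to 9.06). Retnla without Siglec-Fint/CD101- replicate 1 had a log2 fold change of 5.12 (adjusted p = 0.0558), and Chil3 one of 1.29 (adjusted p = 0.267).

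Type 2 genes went both ways in this comparison too, and as a list they lay above other genes, whose median was negative. Chil4 rose from 0.825 ± 1.55 to 211 ± 111 CPM (7.91 ± 1.41), and Ccl8, a chemokine for eosinophils and T cells, had 120 counts in Siglec-Fint/CD101- and 1 in resident libraries, a ratio of 1930 (340 to 76800; log2 fold change 9.91, and from 7.44 to 10.87 with 1 library left out). Adjusted over the list alone, 5 of 16 members rose and 3 fell (adjusted p = 1.75e-06 for Retnla, 0.000166 for Chil3, 0.000261 for Chil4 and 0.000672 for Ccl8), and over all genes Retnla and Chil3 passed. Camera placed the list above other genes (adjusted p = 9.03e-06, and adjusted p = 0.304 with an estimated correlation), with a mean of 1.23 and a median of -0.03. The sign of that median was not stable, at -0.55 without Siglec-Fint/CD101- replicate 1, 0.57 without replicate 2 and 0.35 with RLE normalization. Simulated 4-fold changes were recovered in 0% of genes in this comparison, 16-fold in 32.8% and 64-fold in 57.6%.

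Some genes of eosinophil identity were lower in Siglec-Fint/CD101- than in resident libraries. Gata2, a transcription factor of the eosinophil lineage, went from 80.7 ± 29.0 to 5.04 ± 6.24 CPM (-4.01 ± 1.07, and from -7.04 to -3.11 with 1 library left out). Il1rl1, the IL-33 receptor, had 2016 and 3 counts, a ratio of 41.8 (14.3 to 203), and Trib1, a pseudokinase needed in eosinophil differentiation, went from 85.5 ± 27.2 to 16.6 ± 15.6 CPM (-2.37, and from -3.99 to -1.65 with 1 library left out). With Siglecf, these were the 4 of 13 eosinophil receptors and lineage factors that fell adjusted over the list alone, and 0 of 13 passed over all genes. Camera did not call that list (adjusted p = 0.177, and adjusted p = 0.698 with an estimated correlation; median -1.88), and in the granule list 0 of 4 passed, with a mean of 0.29. Ltb4r1, the leukotriene B4 receptor, had 1901 counts in resident and 0 in Siglec-Fint/CD101- libraries (at least 39.4-fold lower; adjusted p = 0.00518 over 19 lipid mediator genes). Fpr1 had 1554 and 0 counts (at least 32.2-fold lower), Clec12a, an inhibitory lectin receptor, 1179 and 0 counts (at least 24.4-fold lower), and Il13ra1, a chain of the IL-13 receptor, 883 and 0 counts (at least 18.3-fold lower). Timp1, an inhibitor of metalloproteinases, had 66 counts in Siglec-Fint/CD101- and 3 in resident libraries (354-fold, 116 to 1760). Cd300lb, an activating receptor of myeloid cells, went from 5.18 ± 3.30 to 59.6 ± 23.7 CPM (adjusted p = 0.044 over its list alone). In the inflammatory-subset list 3 of 7 fell, and in the resident-subset list 0 of 6 passed.

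Mitochondrial protein genes again rose in 12 of 13 members adjusted over the list alone, with 0 over all genes. Examples were mt-Co1 (1.68 ± 0.34, and from 0.98 to 2.08 with 1 library left out) and mt-Co3 (1.57 ± 0.34), subunits of cytochrome c oxidase. The list's median was 1.21 (camera adjusted p = 6.61e-10, and adjusted p = 0.605 with an estimated correlation), but 0.12 without Siglec-Fint/CD101- replicate 2 (camera adjusted p = 0.0961). Markers of B cells also lay above other genes (median 1.67; camera adjusted p = 0.00012, and adjusted p = 0.304 with an estimated correlation), with a median of 0.62 without Siglec-Fint/CD101- replicate 1 and 1.33 without replicate 2. Ighm, the IgM heavy chain, rose from 57.3 ± 19.0 to 360 ± 254 CPM (log2 fold change 2.65, and from 1.60 to 3.22 with 1 library left out) as the 1 of 14 members past the threshold over the list alone, and 0 passed over all genes. The B cell sum was 208.6 ± 65.5 CPM in resident and 858 ± 413 CPM in Siglec-Fint/CD101- libraries. Endothelial and fibroblast markers (median 0.39; camera adjusted p = 0.00146, and adjusted p = 0.698 with an estimated correlation) had 0 of 19 members past the threshold either way, and without Siglec-Fint/CD101- replicate 2 their adjusted p was 0.436 and their median -0.32, opposite in sign, against 0.91 without resident replicate 5. Cytosolic ribosomal protein genes were called up against other genes (adjusted p = 0.015, and adjusted p = 0.932 with an estimated correlation) with a median of -0.06 and a mean of -0.13, near 0 and above the all-gene median of -0.997. The median was 0.32 with RLE normalization, 0.17 without Siglec-Fint/CD101- replicate 2 and 0.09 without resident replicate 4. Without Siglec-Fint/CD101- replicate 1 their direction turned (adjusted p = 0.977), and without resident replicate 5 (0.0881) or SiglecFhi/CD101+ replicate 1 (0.0799) or 2 (0.122) the call was lost. The remaining 30 lists had a smallest camera adjusted p of 0.0512, and 12 of 35 lists held a member that passed over the list alone.

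Comparing the calls of both subsets against the same resident libraries, Retnla and Igha were the 2 genes higher in both, and 0 were lower in both. Independent lists of these sizes would share 0.00101 genes, but these lists use the same resident libraries and are not independent. Simulated subsets without an effect shared 0, which does not show what the shared libraries add when genes are called. With the resident libraries divided so that each subset had its own pair, the 6 possible assignments gave 1 to 2 shared genes, and Retnla was shared in 6 of 6.

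The third comparison set the subsets against each other. Arhgap1 (ENSMUSG00000027247; chromosome 2, 91649860 to 91672326) was at 271 ± 112 CPM in SiglecFhi/CD101+ libraries (935 counts) and had 2 counts in Siglec-Fint/CD101- libraries, a ratio of 396 (109 to 3270; adjusted p = 0.00957). It was the 1 gene of 11828 called higher, and 0 were called lower, by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1180 higher and 941 lower genes, where chance gives 591 in all. That excess depended on the fit. At this level a fit on the 2 subsets alone had 320 of 5490 tested genes, limma-voom had 750 and DESeq2 had 2993. DESeq2 called 650 higher and 483 lower, and limma-voom 0 in both directions. No Arhgap1 call was made without either Siglec-Fint/CD101- library (adjusted p = 0.0916 and 0.0761), or without SiglecFhi/CD101+ replicate 2 (0.0935), although its log2 fold change, 8.62 over all libraries, was 8.69, 8.43 and 8.05 there. The 3 lower genes with the smallest p did not pass: Higd2a with 451 counts in Siglec-Fint/CD101- and 4 in SiglecFhi/CD101+ libraries (adjusted p = 0.0918), Myo1e, an unconventional myosin, with 348 and 5 (0.106), and C1qc, a chain of complement C1q made by macrophages, with 404 and 10 (0.106). Retnla was at similar levels in both subsets (2240 ± 1050 and 1750 ± 1090 CPM).

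A few eosinophil genes were higher in SiglecFhi/CD101+ than in Siglec-Fint/CD101- libraries adjusted over the list alone, 0 passed over all genes, and others went the opposite way. Prg2 had 458 and 4 counts, a ratio of 97 (37.6 to 357; adjusted p = 0.00156 over 4 granule genes; log2 fold change 6.68, and from 4.8 to 7.45 with 1 library left out), and Gata2 and Siglecf were the 2 of 13 eosinophil receptors and lineage factors that rose (adjusted p = 0.0298 each). Gata2 was at 88.2 ± 28.2 and 5.04 ± 6.24 CPM (log2 fold change 4.14, and from 3.13 to 7.06 with 1 library left out). The ribonuclease genes Ear6 (0 and 118 counts) and Ear1 (28 and 98 counts), whose reads may be shared, had fewer counts in SiglecFhi/CD101+ libraries and did not pass. Camera called neither the granule list (adjusted p = 0.886, and adjusted p = 0.997 with an estimated correlation), whose median was -1.25 against camera's upward direction, nor the receptor and lineage list (0.192, and 0.65 with an estimated correlation; median 1.18). Cxcr2, a chemokine receptor of neutrophils and other granulocytes, had 124 and 0 counts (at least 35-fold higher), and Ltb4r1 59 and 0 counts (at least 16.7-fold higher). In the IL-5, IL-3 and GM-CSF list, Socs2, a STAT5-induced inhibitor, rose (3.92 ± 1.12) while Csf2ra (-4.31 ± 1.14, and from -7.98 to -2.41 with 1 library left out) and Socs3 (-2.97 ± 0.84) fell. Socs2 ranged from 3.17 to 5.13 with 1 library left out. H2-Ab1 was the 1 of 13 class II genes that fell (-1.70 ± 0.41; adjusted p = 0.0106). Also lower in SiglecFhi/CD101+ libraries were Ptger4, with 1 count against 153 (ratio 181, 31.9 to 7180), Il6 with 2 against 119 (70.3, 19.0 to 587; log2 -7.00 to -4.59 with 1 library left out), and Egr2, an early growth response factor, with 0 against 136 (at least 53.5-fold). Stard4, a cholesterol carrier, had 0 against 86 counts (at least 33.9-fold), and Slc3a2, an amino acid transporter chain, was at 96.6 ± 42.8 against 280 ± 86.1 CPM. Among markers of other cell types, C1qc of macrophages (47.7-fold, 25.7 to 100), Itgae of dendritic cells (1 against 129 counts; log2 -11.23 to -4.91 with 1 library left out) and Kit of mast cells (2 against 68 counts) were lower over their lists alone. In the resident-subset list 0 of 6 passed, and in the inflammatory-subset list Siglecf rose while Il6 and Slc3a2 fell, among 7.

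Cytosolic ribosomal protein genes were the 1 of 35 lists with a camera call between the subsets, lower in SiglecFhi/CD101+ libraries (median -0.61; adjusted p = 0.000115, and adjusted p = 0.65 with an estimated correlation). With 1 library left out the median was -0.99 without Siglec-Fint/CD101- replicate 2, -0.94 without SiglecFhi/CD101+ replicate 1 and -0.41 without Siglec-Fint/CD101- replicate 1. Rpl37 and Rplp2, proteins of the large subunit, were at 199 ± 22.5 and 104 ± 20.3 CPM in SiglecFhi/CD101+ and at 626 ± 309 and 350 ± 12 CPM in Siglec-Fint/CD101- libraries, with log2 ranges of -2.17 to -1.08 and -2.03 to -1.62 with 1 library left out. Of the 74 members, 0 passed over all genes or adjusted over the list alone, and without Siglec-Fint/CD101- replicate 1 the camera adjusted p was 0.0618. The other 34 lists had a smallest adjusted p of 0.095, and 13 of 35 lists held a member that passed over the list alone. Simulated 4-fold changes in this comparison were recovered in 1.49% of genes, 16-fold in 22.4% and 64-fold in 48.5%.

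**Figure D3:**
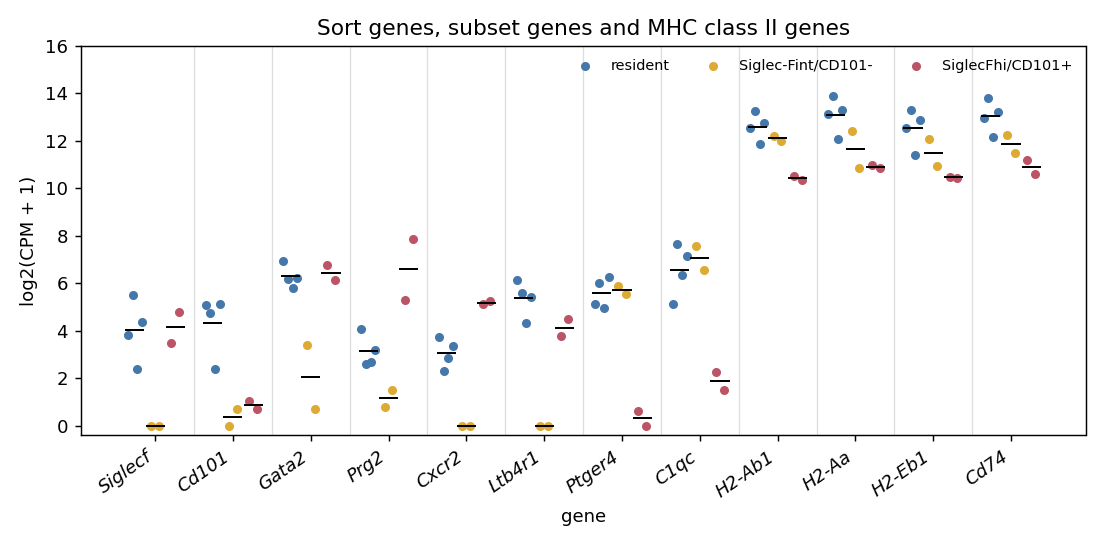
Points are single libraries and black lines group means of log2(CPM + 1) for the sort genes Siglecf and Cd101, genes named between the subsets, and 4 MHC class II genes, coloured by group. Siglecf, Cxcr2 and Ltb4r1 have 0 counts in both Siglec-Fint/CD101- libraries, and Ptger4 has 1 count over both SiglecFhi/CD101+ libraries.

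Markers of other cell types were present in all libraries and varied most between resident libraries for lung structure and blood. Epithelial markers, among them the club cell gene Scgb1a1 and the surfactant gene Sftpc, summed to 7030, 1273, 15450 and 1892 CPM in resident replicates 3 to 6, to 5133 and 8454 CPM in Siglec-Fint/CD101- and to 5890 and 5305 CPM in SiglecFhi/CD101+ libraries. Erythroid and platelet markers summed to 9796 CPM in resident replicate 3 and to 999.3 to 2374 CPM in the other resident libraries. Neutrophil markers were at 330.0 ± 130 CPM in resident, 1354 ± 396 CPM in Siglec-Fint/CD101- and 873 ± 404 CPM in SiglecFhi/CD101+ libraries. Of these, Lcn2, an iron-sequestering protein, and Retnlg, a resistin-like protein of neutrophils, rose and Cxcr2 fell in Siglec-Fint/CD101- against resident libraries adjusted over the list alone (adjusted p = 0.0162, 0.0258 and 0.0258), and 0 of 10 passed over all genes. The log2 fold change of Lcn2 was 3.54, and from 1.96 to 4.88 with 1 library left out, and that of Retnlg 2.08, and from 1.20 to 2.62. Cd4, the T helper cell co-receptor, was at 1.76 ± 1.58 CPM in resident and 66.1 ± 11.5 CPM in SiglecFhi/CD101+ libraries (adjusted p = 0.0261 over its list alone). In Siglec-Fint/CD101- libraries Cd4 was at 0 and 144.7 CPM, so its rise there (adjusted p = 0.0326 over its list alone) came from replicate 2, and without that library its log2 fold change was -6.78. Mrc1, the mannose receptor of macrophages, had 1746 counts in resident and 3 in SiglecFhi/CD101+ libraries, a ratio of 42.7 (14.6 to 207), and C1qc was 43.8-fold lower there (23.8 to 91.4), each past the threshold over its list alone.

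**Figure D4:**
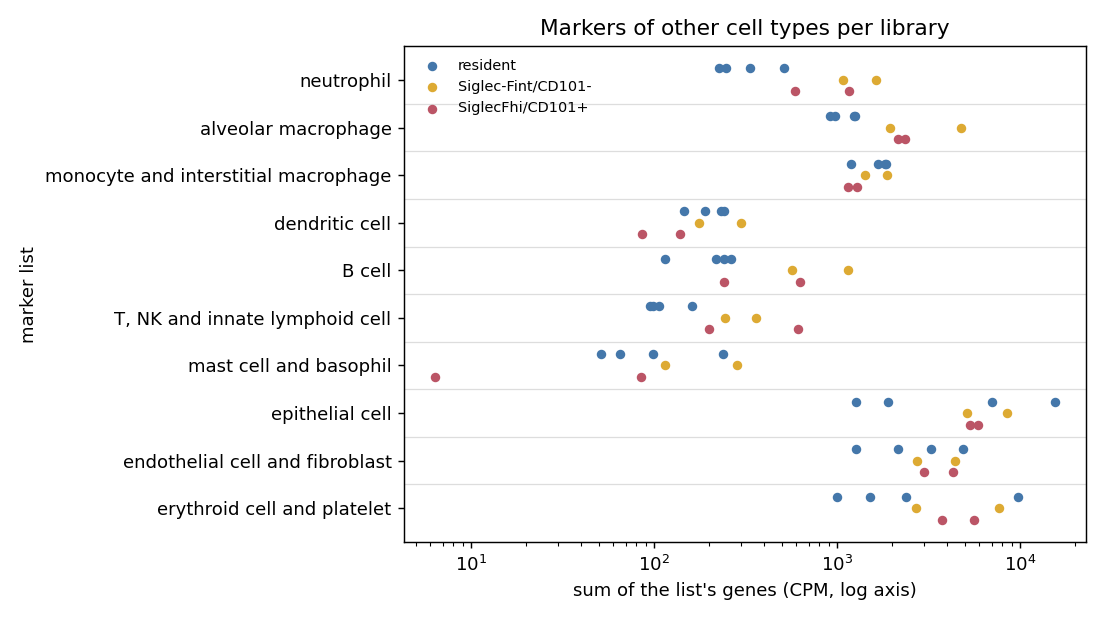
Each point is the summed CPM of 1 marker list in 1 library, on a log axis, with the 10 lists of other cell types at separate heights and groups as colours. Epithelial sums run from 1273 to 15450 CPM among resident libraries and from 5133 to 8454 CPM among subset libraries.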

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

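Of the tests in this part, those on alveolar macrophage RNA, plasma cell RNA, sex, dilution by structural cells and dendritic cell RNA were chosen only after the result was seen. The others were written down before, although the mitochondrial test uses a fit that was chosen only after the result was seen. The 4 genes called with both subsets as 1 group were also known when the prediction for the other splits was written.

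Retnla, Igha and Chil3 were higher in all 4 subset libraries (at least 982, 130 and 1530 CPM) than in all 4 resident libraries (at most 79.7, 11.6 and 708 CPM). RNA of alveolar macrophages, which also carry Siglec-F and so could pass the sort, was tested only as a rise of the whole macrophage list. Its 16 other members had a median log2 fold change of -1.04 in SiglecFhi/CD101+ libraries (95% interval -2.67 to 0.64). In Siglec-Fint/CD101- libraries their median was -0.80 (-4.05 to 0.49). Both lay below the 1.69 and 2.31 of Chil3, but these intervals run over genes and do not measure the spread between libraries. The medians of all tested genes were also negative, at -0.716 and -0.997, so a low list median says little alone. The other members summed to 399 to 549 CPM in resident and 198 to 415 CPM in subset libraries, with Flt1, Car4 and Lpl the most abundant. Their sum thus did not rise with Chil3, which argues against more macrophage RNA of unchanged make-up. Macrophages with more Chil3 or Retnla but no more of the other markers were not tested for, so macrophage RNA stays open as a source of both. RNA of plasma cells is a candidate source of Igha, since Jchain, the joining chain of secreted IgA, was 4.16 times higher in the lowest subset library than in the highest resident library, though it had only 89 and 123 counts in the subsets. Sex cannot be told apart from the groups, because a single resident library had Xist without Ddx3y, and it held Retnla at 11.9 CPM. A difference in treatment, which the labels do not give, and a difference between the sorted populations themselves stay open and were not tested.

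MHC class II genes were lower in SiglecFhi/CD101+ than in resident libraries, with 7 of 13 past the threshold over the list alone. In Siglec-Fint/CD101- against resident libraries the list's median was -1.22, near the -0.997 of all genes, with 0 of 13 past that threshold. The list summed to 32960 ± 14300 CPM in resident (15930 in replicate 5), 15610 ± 6205 in Siglec-Fint/CD101- and 6933 ± 868 in SiglecFhi/CD101+ libraries. With mitochondrial genes left out, the list's median in SiglecFhi/CD101+ against resident libraries was -2.13, where the median of all genes was -0.55. Class II genes thus fell against other genes in that fit, although leaving out either SiglecFhi/CD101+ library put the all-gene median below the list's. TMM scaling already offsets much of the mitochondrial share in the main median of -2.22. The test could therefore hardly move the list and does not decide on a larger mitochondrial share as the cause. For dilution by lung structural cells, epithelial and class II sums had a Spearman correlation of -0.52 over 8 libraries (exact two-sided permutation p = 0.197), which does not decide. Pearson's was -0.53 (exact permutation p = 0.18), and -0.5 without resident replicates 5 and 4. It was the 1 such relation computed, and the 4 resident libraries alone are too few. Epithelial sums in resident replicates 3 and 5 (7030 and 15450 CPM) exceeded those in SiglecFhi/CD101+ libraries (5890 and 5305 CPM). Class II sums were 30110 and 15930 against 7547 and 6320 CPM, which argues against epithelial RNA as the whole cause. Endothelial and fibroblast sums overlapped (1271 to 4882 against 4321 and 3000 CPM), so dilution by those cells stays open. More dendritic cell RNA in resident libraries also stays open, since the dendritic cell list had a median of -2.08, between the -0.72 of all genes and the -2.22 of the class II list, with 10 members tested. A difference between the eosinophil populations was not tested apart from these.

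Between the subsets, 182 genes were near 0 (under 3 CPM) in both libraries of one subset and abundant (above 20 CPM) in both of the other, 106 of them in SiglecFhi/CD101+ and 76 in Siglec-Fint/CD101- libraries. Arhgap1, Cxcr2 and Ptger4 show this pattern. Loss of transcripts at random in small libraries may account for most of it, since regrouping the same libraries across the subsets gave 147 and 144 such genes, so the real grouping had 1.24 times the higher of these. Sequencing depth cannot be told apart: thinning to the smallest library left 183 genes, 1.01 times as many, but it removed only 0.24% and 0% of the counts of a library in each subset, so the depth shared by the subsets was not varied and the bound set before did not test it. A true difference between the subsets would add to the real grouping, and its share was not tested.

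With both subsets taken as 1 group, a comparison added after seeing the data, 4 genes (Retnla, Igha, Chil3 and Gm26870) of 8508 were higher than in resident libraries and 0 lower by edgeR's quasi-likelihood test, with 136 higher and 685 lower at an unadjusted p under 0.05. Chance cannot be excluded: 2 of the 35 splits of the 8 libraries into 4 and 4 gave as many genes, and the highest of the other splits gave 4. That other split set resident replicate 3, Siglec-Fint/CD101- replicate 2 and both SiglecFhi/CD101+ libraries against the rest, and its 4 genes were mt-Nd2, mt-Nd1, mt-Cytb and mt-Atp6, with 0 of the real split's genes among them.

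Single resident libraries stood far from the other 3 in 10 of 108 values screened by Dixon's test, where 1 in 20, or 5.4, is what chance gives for independent normal values. The excess cannot be read from these counts, since Xist, Clca1, Epx, Hba-a1 and Jchain entered the screen only because their values had been seen. Genes with 3 or fewer counts in every resident library were left out after a first look at the screen. Gaps are to the nearest library, divided by the group's range. In resident replicate 3, Xist was at 332 CPM against 0 to 0.0786 CPM (gap 1), Hba-a1 of haemoglobin at 3210 against 346 to 624 CPM (0.903), the erythroid and platelet sum at 9800 against 999 to 2370 CPM (0.844), and Jchain at 2.67 against 0 CPM (1). In resident replicate 5, Igha was at 11.6 against 0.236 to 1.8 CPM (0.863), Lcn2 at 68.5 against 5.82 to 12.7 CPM (0.89), Chil4 at 3.15 against 0 to 0.0786 CPM (0.975) and Epx at 1.75 against 0 CPM (1). In resident replicate 4, the T, NK and innate lymphoid sum was at 162 against 95.6 to 106 CPM (0.843), and Clca1 at 1.18 against 0 to 0.0665 CPM (0.944).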

How the results depend on the processing

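All alternatives were set before the data were examined except leaving out mitochondrial genes and leaving out resident replicates 3 and 5 together, which, like the tests on them, were chosen only after the result was seen. The counts of called genes, 1 between the subsets, 3 in SiglecFhi/CD101+ against resident and 7 in Siglec-Fint/CD101- against resident, moved in 36 of 67 alternatives; the cause was not tested except where stated. In the order of these comparisons, DESeq2 called 1133, 1076 and 628 genes, no filter gave 85, 370 and 136 with 21197 genes tested, and fits on the compared groups alone gave 0, 1 and 0. limma-voom called 0 between the subsets and 2 in Siglec-Fint/CD101- against resident libraries. That last comparison gave 1 with non-robust fits, with the stricter filter, at an adjusted p under 0.01 and with glmTreat. Library totals alone gave 7 in SiglecFhi/CD101+ against resident (2 higher, 5 lower, against 3 and 0) and 3 in Siglec-Fint/CD101- against resident (1 higher, 2 lower, against 4 and 3), where RLE gave 7 higher and 2 lower. Thinning gave 4 between the subsets. For counts, leaving out each library gave 0 to 2, 1 to 133 and 0 to 9 genes, with 131 and 133 for SiglecFhi/CD101+ against resident without Siglec-Fint/CD101- replicate 1 or 2, libraries that are in neither group; the shared spread and the filter, which then kept 14968 and 14962 genes, changed together and were not told apart. Without resident replicates 3 and 5 the first 2 comparisons gave 0 and 10. With the replicate number of the subsets as a block, tried only for the comparison between them, 0 genes were called (Arhgap1 adjusted p = 0.0598). The ribosomal list kept its camera call there (adjusted p = 1.13e-05). The labels do not pair these libraries, and the deviations of equal numbers correlated at 0.007 across genes. Of the called genes, Gm26870 passed in 22 of 22 alternatives in SiglecFhi/CD101+ against resident, and Retnla in 20 of 22 in each comparison with resident, with log2 fold changes of 4.49 to 6.05 and 4.96 to 6.30. Igha passed in 9 of 21 in each, Arhgap1 in 16 of 23 between the subsets and 7 of 22 in Siglec-Fint/CD101- against resident, and, in that last comparison, Chil3, Tppp3 and Rnase2a in 8 of 22 and Ywhag in 10 of 22. Reversed was Siglecf in SiglecFhi/CD101+ against resident with RLE (0.36), upper-quartile (0.09), DESeq2 (0.35), limma-voom (0.17), thinning (0.28) and without resident replicate 4 (0.69) or SiglecFhi/CD101+ replicate 1 (0.32; range over libraries left out -1.11 to 0.69). Cd4 in Siglec-Fint/CD101- against resident reversed without replicate 2 of that subset (-6.78; range -6.78 to 6.26), its only library there with counts, and the ribosomal list there reversed with fry (adjusted p = 0.789) and without Siglec-Fint/CD101- replicate 1 (0.977; range 0.000154 to 0.977). The 9 camera calls were all lost with an estimated correlation, and none of them passed fry's directional test, which called 10 other lists in SiglecFhi/CD101+ against resident. Fry's mixed test, for change in either direction, passed 7, 28 and 14 of 35 lists in the order of the comparisons above. Class II (0.0145) and mitochondrial protein genes (0.0408) were among the 28 in SiglecFhi/CD101+ against resident, so passing hardly sets them apart. Type 2 genes (0.000517) were among the 14 in Siglec-Fint/CD101- against resident. Over all alternatives 33 list results lost their call in the same direction and 2 reversed. The shared count of 2 genes fell to 1 in 4 of 6 divisions of the resident libraries. Depth limits single genes most in the subset libraries, where 3 counts are 1.59 to 2.18 CPM.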

Other observations

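The tests of other gene groups were planned, and Clca1, Slc26a4, Bpifa1, Jchain, Xist and Ddx3y were chosen only after their values were seen. In several planned lists no gene passed in any of the 3 comparisons, over all genes tested or adjusted over the list alone. Among these, with their tested members, were the interferon response (35), MHC class I presentation (16), glycolysis (22), hypoxia response (15), nuclear oxidative phosphorylation (41), cell cycle (23) and endoplasmic reticulum stress (22) lists, by edgeR's quasi-likelihood test. As lists, MHC class I (adjusted p = 0.0298), hypoxia (0.0298), cell cycle (0.0243) and endoplasmic reticulum stress genes (0.0243) were nonetheless lower in SiglecFhi/CD101+ than in resident libraries by fry, where the median of all tested genes was itself -0.72, and camera called none of them. Interferon response genes summed to 1569 ± 462 CPM in resident (SD, n = 4), 2822 ± 366 CPM in Siglec-Fint/CD101- (n = 2) and 1788 ± 335 CPM in SiglecFhi/CD101+ libraries (n = 2). Nuclear genes of oxidative phosphorylation summed to 2508, 2597 and 2128 CPM in the same order, where mitochondrially encoded proteins summed to 122700, 292000 and 351600 CPM. Simulated changes of 4-fold were recovered in at most 1.49% of genes, so smaller shifts within these groups would not have been called.

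A pair of genes known from mucus-producing airway cells, for which no list was tested, had counts in subset libraries. Clca1, a secreted regulator of goblet cells, was at 84.3 and 9.93 CPM in the Siglec-Fint/CD101- and 124.6 and 23.8 CPM in the SiglecFhi/CD101+ libraries, against at most 1.18 CPM in resident libraries. Slc26a4, the anion exchanger pendrin, was at 85.8, 19.3, 53.5 and 0 CPM in those subset libraries and at most 0.167 CPM in resident libraries. Bpifa1, a secreted airway protein, had 4445 counts in resident, 115 in Siglec-Fint/CD101- and 2 in SiglecFhi/CD101+ libraries, and the epithelial sums were 6410 CPM in resident, 6794 CPM in Siglec-Fint/CD101- and 5598 CPM in SiglecFhi/CD101+ libraries. Jchain was at 49.4 and 13.0 CPM in the Siglec-Fint/CD101- and 11.1 and 62.2 CPM in the SiglecFhi/CD101+ libraries, against 2.67 CPM in resident replicate 3 and 0 CPM in the other resident libraries.

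Transcripts of the sex chromosomes differed between libraries of the same group. Xist, which silences an X chromosome in females, was at 332 CPM in resident replicate 3 and at most 0.0786 CPM in resident replicates 4 to 6, which held the Y-linked Ddx3y at 44.7, 75.0 and 56.9 CPM. Both Siglec-Fint/CD101- libraries held Xist (15.3 and 104 CPM) and no Ddx3y counts. SiglecFhi/CD101+ replicate 1 held Xist at 35.5 CPM without Ddx3y, and replicate 2 held both, Xist at 104 CPM and Ddx3y at 26.2 CPM.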
